A study of Mus musculus with 30 samples.

How the data were processed

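The series holds 30 samples in 10 groups of 3 and 4 experiments: 18 RNA-seq libraries, 6 H3K9me3 ChIP-seq libraries and 6 input libraries. RNA was prepared with a Direct-zol kit and sequenced by Amera Health; ChIP was done by Diagenode with the iDeal kit for histones and the MicroPlex v3 library kit. Samples were grouped by cell line, genotype and treatment as the labels give them.

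For RNA, the authors deposited raw counts per Ensembl gene, 1 table per library with 55487 genes, of which 55141 had a symbol in the annotation used here. Per the labels, the processing involved STAR 2.7.10b, Picard 3.0.0, StringTie 2.2.1, featureCounts 2.0.6, HTSeq 2.0.3 and DESeq2 1.18.1 for RNA, and Bowtie, DiffBind and ChIPseeker for ChIP, with builds GRCm38 and mm10. Which tool made the counts and which called the ChIP regions is not given in the sources used here, nor is the strand setting, so values of antisense and overlapping genes are uncertain. Near-identical paralogs (globin genes, Zscan4 genes, Defa30) are uncertain as well, since how shared reads were counted is not stated.

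For ChIP, the authors deposited a list of enriched regions per library with ChIP and input counts per region. Per the file headers each region also has a log2 fold change, a p-value with its FDR, and a score. The log2 fold change equals the log2 ratio of ChIP to input counts minus 1 constant per library, the score is a rescaled log2 fold change, and every region has an FDR of 0.05 or less. Regions consist of whole 200 bp windows. The input libraries have no values of their own and were not used.

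RNA was analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept with filterByExpr by group, libraries were scaled by TMM, and each comparison was tested by the quasi-likelihood F test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment and a threshold of 0.05. DOX in iETV2, DOX in the H188A line and DKO were fitted on their own 6 libraries each. The interaction of line and treatment and the comparisons between the lines were fitted on the 12 libraries of experiments 1 and 2 with 4 group means. SE is the log2 change divided by the square root of the F statistic. CPM are counts scaled by the library total, without TMM factors, so a log2 change can differ slightly from the ratio of CPM.

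Gene lists were tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison; lists with fewer than 3 measured genes were not tested. The 18 lists were endothelial, hematopoietic, VEGF and Notch signalling, pluripotency, primitive streak, cardiac mesoderm, endoderm, neuroectoderm, trophoblast, fibroblast (feeder cells), 2-cell-like, germline, H3K9 demethylases, H3K9 methylation genes, p53 targets, integrated stress response, mitochondrially encoded, and glycolysis and hypoxia. Lists for motile cilia and node, imprinted genes, HOX clusters and hindbrain progenitors were added after seeing results. Each list call is given also with a correlation estimated from the residuals. With it the calls that hold are endothelial, hematopoietic, primitive streak, cardiac, neuroectoderm and glycolysis for DOX in iETV2, and 9 lists in DKO; none hold in the H188A line. Member counts are given over all tested genes and, where stated, adjusted over the list alone.

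Genes named in the text follow a rule: Etv2, Kdm4a, Kdm4b and Kdm4c; a panel of Kdr, Tal1, Gata2, Fli1, Pecam1, Cdh5, Pou5f1, Nanog and Sox2; the 6 largest changes per direction among genes with adjusted p under 0.05, an average log2 CPM of at least 1, groups that do not overlap and an informative symbol; and up to 4 members of each called list with the smallest adjusted p in the direction of its call. The result of 1 gene that met this rule is not reported here, although the gene stayed in all tests and lists. Genes of the added lists, Flt1, Apln and Lhx1 in iETV2, Xist and other sex-linked genes, Hprt, Meg3 and Shh were named after their values were seen. The comparisons with their tests, the 18 lists, the naming rule and all alternatives but those named below as added were chosen before the data were examined. Several tests of explanations were chosen later and are named as such where they are given.

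The response in DKO of genes that rose or fell with DOX in iETV2 was tested with camera on both sets, and overlaps of calls with Fisher's exact test, two-sided, beside the number expected for independent calls. ChIP groups were compared by two-sided exact permutation tests of the mean number of regions and covered length. Regions of all 6 libraries were merged where they shared at least 1 bp. The annotation (GRCm38) gave gene positions without strand, so the planned window of 5 kb around the start site became 5 kb from either gene end; 84.9 to 85.4% of tested genes had a position. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for ChIP and figures. Bootstrap intervals are 95% intervals from 2000 draws of genes. They treat genes as independent, so they are too narrow for lists of correlated genes.

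Depth was 40334911 to 68970038 counts per library, and 0 counts in a group was treated as a floor of 3 counts over the group. For 1 to 3 counts a ratio with its 95% counting interval is given. Intervals and floors cover counting error only. The pipeline was tested on simulated counts, drawn from the mean and fitted spread of each gene and the library sizes, with changes added to some genes. Such counts follow the test's own model and lack any other differences between the real replicates. Changes of 4-fold were recovered in 75.8% of genes for iETV2, 80.3% for the H188A line, 68.2% for the interaction and 89.4% for DKO, and changes of 1.5-fold in 46.3%, 43.3%, 13.4% and 55.2%. In the same order 6, 15, 8 and 16 unchanged genes were called. A list of 25 unchanged genes had a camera p of 0.493, 0.0236, 0.523 and 0.468, and of 1000 such random lists per comparison 2, 0, 9 and 0 had a p under 0.05. Simulated genes vary independently, so this says nothing of lists of correlated genes.

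Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no low-count filter, a stricter one (CPM of at least 1 in 3 libraries), an absolute log2 change of at least 1, the replicate number as a block, all libraries in 1 fit, each library left out, and for ChIP a stricter region threshold, autosomes only, other overlaps and windows. Added after seeing the data were the summed CPM of 1449 olfactory, vomeronasal and trace-amine receptor genes as a covariate, and protein-coding genes only. Differential binding was not analysed here, since it needs read counts of all libraries over shared regions.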

Results

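The series asks how ETV2 (also called ER71), an ETS-family transcription factor needed for the first blood and endothelial cells, works together with KDM4A, an enzyme that removes methyl groups from lysine 9 of histone H3. All samples were labelled as mouse embryonic stem cells. RNA was sequenced in 18 libraries that form 6 groups of 3. In the iETV2 line, doxycycline (DOX) is given to switch on Etv2, and the groups were iETV2 without and with DOX. The second line, iETV2-KDM4A (H188A), is called the H188A line here after its KDM4A variant, a substitution in the iron-binding catalytic site, and was also sampled without and with DOX. The last 2 groups were control cells and cells labelled KDM4A/4C DKO, a double knockout of Kdm4a and its relative Kdm4c. H3K9me3, the repressive mark trimethylated at lysine 9 of histone H3, was mapped by ChIP-seq in 3 DOX-treated and 3 untreated libraries.

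Library totals were 42586343 to 65950842 counts in iETV2 without DOX and 55006350 to 68222429 with DOX. They were 40334911 to 68970038 in the H188A line without DOX and 48233349 to 62095060 with DOX. The control cells of the DKO experiment had 51011246 to 63246156 counts and the DKO libraries 43246166 to 56671150. In what follows, levels are group means in CPM (counts scaled by the library total) ± SD over 3 libraries, and log2 changes are given ± SE for 3 libraries against 3. "Rose" and "fell" are used for genes with an adjusted p under 0.05. The labels do not state that the replicates are separate cultures, so each p measures the spread between samples only.

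Experiment 1 addressed what DOX changes in iETV2 cells. Etv2 (ENSMUSG00000006311, chromosome 7, 30633616 to 30636509, GRCm38) rose from 2.93 ± 0.18 to 18.6 ± 0.89 CPM, a log2 change of 2.68 ± 0.10 (adjusted p = 1.42e-11). Most genes of the blood and endothelial lists rose with it. Kdr, the VEGF receptor that marks the mesoderm giving rise to both lineages, rose from 7.92 ± 1.3 to 233 ± 4.5 CPM (log2 change 4.89 ± 0.10, adjusted p = 1.99e-14). Tal1, a transcription factor required for blood formation, rose from 0.543 ± 0.34 to 37.9 ± 1.6 CPM, and Cdh5, the adhesion protein VE-cadherin, from 1.05 ± 0.34 to 64.8 ± 1.9 CPM.

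**Figure D1:**
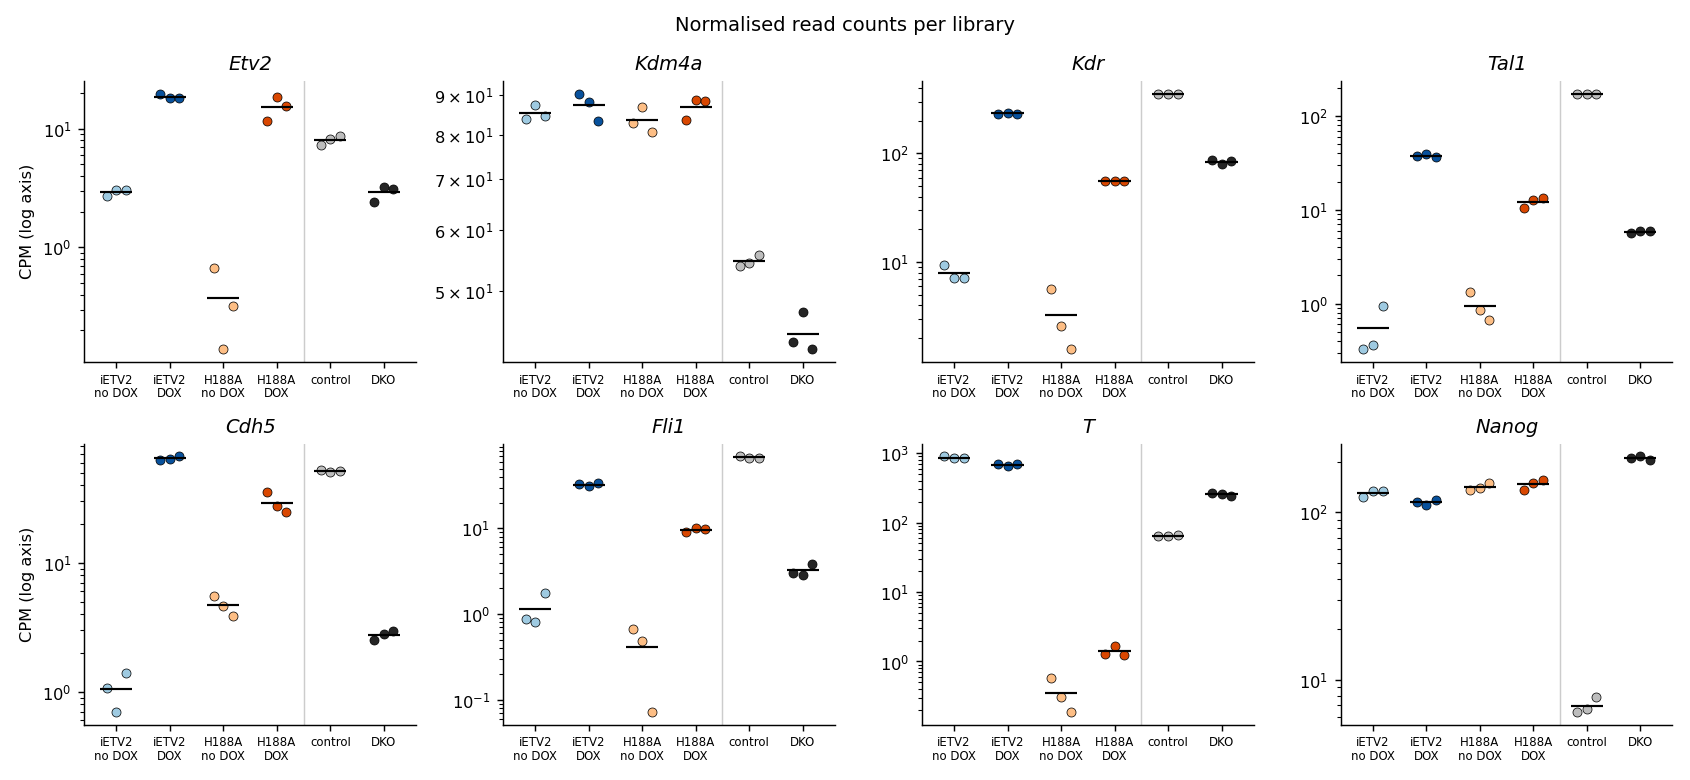
Levels of 8 genes in the 6 RNA groups, in CPM on a log axis; points are libraries and bars are group means (n = 3). Kdr, Tal1, Cdh5 and Fli1 lay higher with DOX than without it in both lines, and lower in the libraries labelled DKO than in their controls, where Nanog lay at 210 against 6.98 CPM.

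Of the 39 measured endothelial genes, 33 rose and 4 fell with DOX in iETV2 (34 and 4 adjusted over the list alone). Their median log2 change was 2.7 (adjusted p = 8.9e-72, and 0.00955 with an estimated correlation). Examples were Fli1 (4.90 ± 0.17), Tek (4.26 ± 0.09), Eng (2.7 ± 0.09) and Pecam1 (2.35 ± 0.09). Of the genes that fell, Flt1 (138 ± 5 to 104 ± 5.5 CPM), Aplnr (263 ± 1.3 to 190 ± 7) and Apln (146 ± 1.6 to 48.9 ± 0.52) were well expressed without DOX. Among the 28 hematopoietic genes, 19 rose and 2 fell (20 and 2 adjusted over the list alone; median 2.42, adjusted p = 4.42e-46, and 0.00955 with an estimated correlation). Besides Tal1 these included Gata2 (4.62 ± 0.25), Lmo2 (3.65 ± 0.09) and the embryonic globins Hba-x (0.267 ± 0.24 to 123 ± 3.7 CPM) and Hbb-bh1 (0.184 ± 0.11 to 80.7 ± 12 CPM). Hbb-y had 837 counts with DOX against 2 without, a ratio of 387 with a 95% counting interval of 107 to 3200. In the VEGF and Notch signalling list 8 of 24 rose, among them Nrp2 (2.73 ± 0.07), Plxnd1 (2.71 ± 0.08) and Flt4 (2.08 ± 0.08), and 6 fell (8 and 7 adjusted over the list alone; median 0.02, adjusted p = 8.63e-10, but adjusted p = 0.0724 with an estimated correlation).

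Other mesodermal genes rose as well. Of the 22 primitive streak genes, which mark the earliest mesoderm, 15 rose and 3 fell (15 and 4 adjusted over the list alone; median 1.07, adjusted p = 9.45e-29, and 0.0364 with an estimated correlation). Evx1 rose by 2.82 ± 0.08 and Mixl1 went from 74.9 ± 4.2 to 317 ± 14 CPM, while T (Brachyury) fell from 862 ± 28 to 679 ± 24 CPM and Lhx1 from 200 ± 9.8 to 96.5 ± 6.7 CPM. In the cardiac mesoderm list 10 of 20 rose and 1 fell (the same counts adjusted over the list alone; median 0.48, adjusted p = 8.95e-24, and 0.019 with an estimated correlation). Hand1, a transcription factor of heart and extraembryonic mesoderm, rose from 0.804 ± 0.18 to 118 ± 3.5 CPM, Foxf1 by 4.89 ± 0.13 and the signalling protein gene Bmp4 by 3.25 ± 0.08. Samsn1 (6.55 ± 0.44) and Hapln1 (6.40 ± 0.18) were also among the 6 largest increases.

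Neuroectoderm genes fell: 13 of 22, with 1 that rose (15 and 1 adjusted over the list alone; median -0.98, adjusted p = 1.99e-12, and 0.00955 with an estimated correlation). Fgf5 went from 136 ± 3.8 to 43.7 ± 2 CPM, Pou3f1 changed by -2.50 ± 0.11, Otx2 by -1.26 ± 0.07 and Six3 by -3.83 ± 0.27. Fgf5 and Otx2 are also epiblast genes, so a fall of this list need not mean a fall of neural cells. In the glycolysis and hypoxia list 19 of 22 fell and 3 did not pass (median -0.80, adjusted p = 1.7e-32, and 0.0423 with an estimated correlation). The glucose transporter gene Slc2a1 went from 928 ± 31 to 295 ± 17 CPM and Ndrg1 from 146 ± 5.3 to 24.7 ± 0.46 CPM. The 6 largest decreases were Dynlrb2 (-5.65 ± 0.37), Cfap206 (-5.58 ± 0.13), Foxd4 (-5.43 ± 0.27), Map3k19 (-4.89 ± 0.29), Iqub (-4.79 ± 0.14) and Dnah5 (-4.74 ± 0.16). Cfap206, Iqub and Dnah5 encode parts of motile cilia.

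In the pluripotency list 14 of 28 rose and 5 fell (14 and 7 adjusted over the list alone; median 0.36, adjusted p = 5.56e-09, but adjusted p = 0.0724 with an estimated correlation). Tbx3, which is also expressed in mesoderm, rose by 4.65 ± 0.11 and Dppa5a by 1.59 ± 0.08, while Pou5f1 fell from 404 ± 29 to 306 ± 45 CPM. Nanog (-0.18 ± 0.07, adjusted p = 0.0607) and Sox2 (-0.21 ± 0.09, adjusted p = 0.0954) did not pass. Kdm4a stayed at 85.3 ± 2 and 87.3 ± 3.6 CPM (log2 change 0.05 ± 0.07, adjusted p = 0.71), while Kdm4b (-0.52 ± 0.07), Kdm4c (-0.44 ± 0.07), Kdm3a (-0.65 ± 0.07) and Kdm7a (-0.61 ± 0.07) fell. In all, 5 of 11 H3K9 demethylase genes fell and 6 did not pass (median -0.10, adjusted p = 0.0315, but adjusted p = 0.586 with an estimated correlation).

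Further lists were called only with the preset correlation. In the germline list 13 of 19 rose (17 adjusted over the list alone), with a median of 1.07 (adjusted p = 0.0024, but adjusted p = 0.0724 with an estimated correlation); Tex11 rose by 2.00 ± 0.35. In the integrated stress response list 15 of 20 rose and 2 fell, among them Slc7a11 (1.45 ± 0.10), Vldlr (0.95 ± 0.07) and Asns (0.82 ± 0.07), with a median of 0.68 (adjusted p = 8.62e-07, but adjusted p = 0.124 with an estimated correlation). RNA of the mitochondrial genome rose in 10 of 13 genes, for example mt-Nd2 at 0.62 ± 0.07 (median 0.54, adjusted p = 0.000737, but adjusted p = 0.191 with an estimated correlation), and its share of all counts went from 4.095 ± 0.06154% to 5.249 ± 0.1052%. In the fibroblast list 10 of 18 rose and 3 fell (median 0.34, adjusted p = 0.000214, but adjusted p = 0.0809 with an estimated correlation), with the matrix protein gene Fn1 going from 1070 ± 30 to 4810 ± 370 CPM. In the trophoblast list, which shares Hand1 with the cardiac list, 8 of 15 rose and 5 fell (median 0.49, adjusted p = 0.0159, but adjusted p = 0.136 with an estimated correlation), with Cdx2 at 1.64 ± 0.10. Not called were endoderm (10 rose and 6 fell of 21; median 0.46, mean 0.05, test direction down, adjusted p = 0.583), p53 targets (adjusted p = 0.636), H3K9 methylation genes (adjusted p = 0.606) and 2-cell-like genes (adjusted p = 0.681).

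Across all genes, 5939 of 22025 tested in iETV2 changed with DOX, 3010 up and 2929 down. Of these, 918 rose and 946 fell with an absolute log2 change of at least 1. The test called 14 of 18 lists with the preset correlation and 6 with an estimated one.

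**Figure D2:**
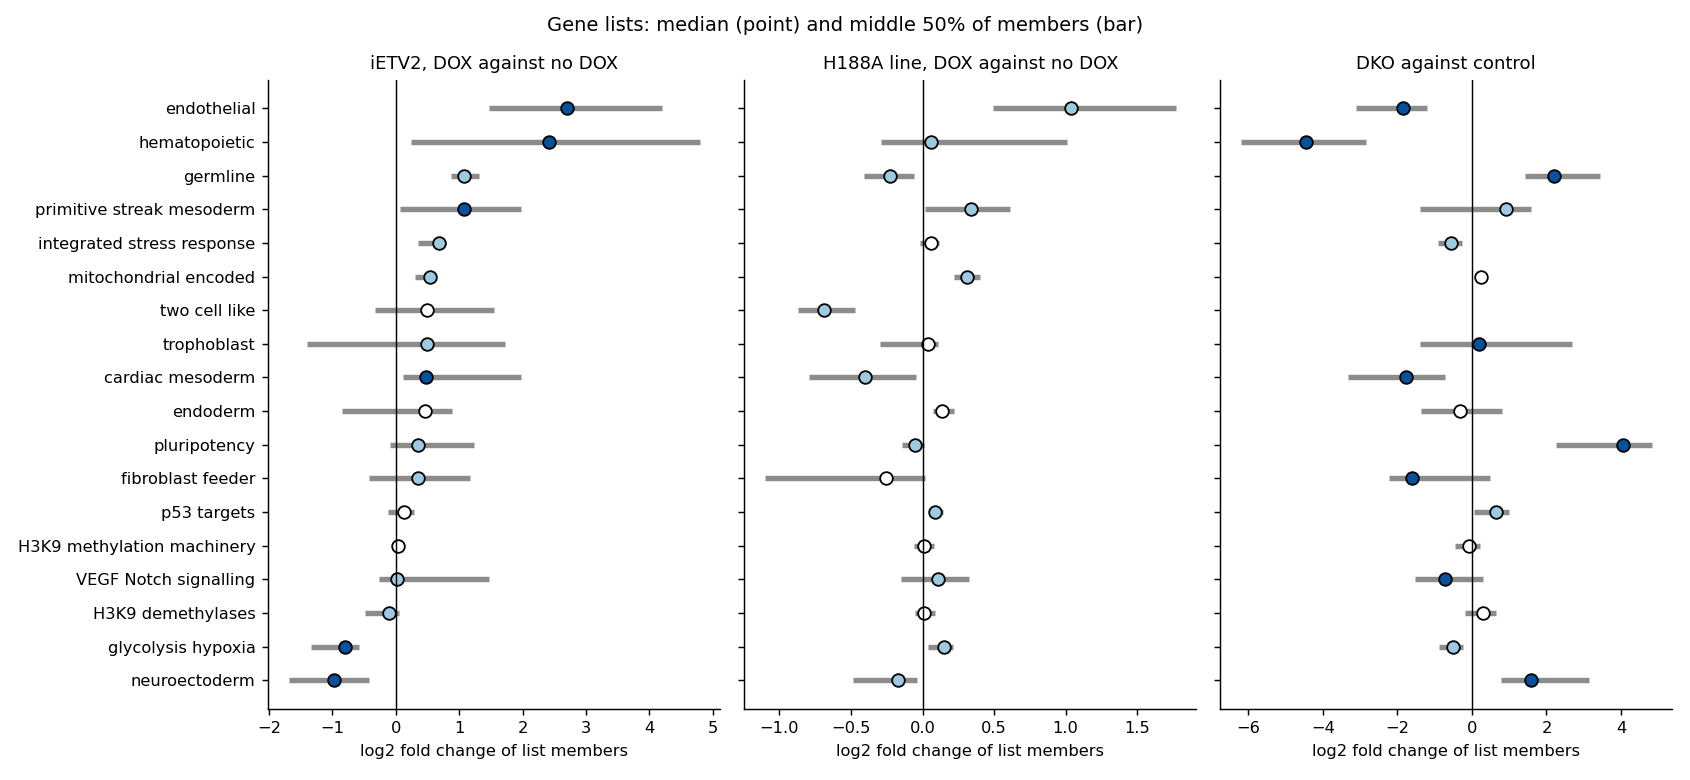
Median log2 change of each gene list (point) with the middle 50% of its members (bar) for DOX in iETV2, DOX in the H188A line and DKO against control, each panel with its own scale. Dark points were called with both correlations, light ones with the preset correlation only, white ones with neither. The endothelial and hematopoietic medians were 2.7 and 2.42 in iETV2, 1.04 and 0.06 in the H188A line, and -1.86 and -4.45 in DKO.

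Experiment 2 put the same question to the H188A line. Etv2 rose there from 0.376 ± 0.27 to 15.2 ± 3.5 CPM (log2 change 5.48 ± 0.35, adjusted p = 7.13e-05). Endothelial regulators rose: Kdr from 3.26 ± 2.1 to 55.8 ± 0.21 CPM, Fli1 from 0.41 ± 0.31 to 9.69 ± 0.58 CPM, Cdh5 from 4.68 ± 0.83 to 29.2 ± 5.5 CPM, Sox18 by 5.20 ± 0.20 and Rhoj by 4.58 ± 0.34. Of the blood genes, Tal1 rose from 0.953 ± 0.35 to 12.2 ± 1.5 CPM, Gata2 by 3.22 ± 0.42 and Lmo2 by 2.36 ± 0.20, and globin genes were not among the genes that rose. Kdm4a RNA was 83.5 ± 3.2 CPM without and 86.9 ± 2.9 CPM with DOX (0.11 ± 0.05, adjusted p = 0.262), beside 85.3 ± 2 and 87.3 ± 3.6 CPM in iETV2. The counts thus show no added Kdm4a RNA in this line and do not show that the mutant was expressed. Counts per gene cannot tell a transgene from the endogenous gene or show a point mutation.

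Among 39 endothelial genes 22 rose and 17 did not pass (27 rose adjusted over the list alone; median 1.04, adjusted p = 1.89e-56, but adjusted p = 0.113 with an estimated correlation). In the hematopoietic list 4 of 23 rose, Hhex (1.03 ± 0.16) being the fourth (6 adjusted over the list alone; median 0.06, adjusted p = 1.04e-05, but adjusted p = 0.366 with an estimated correlation). In the VEGF and Notch list 5 of 24 rose and 1 fell, among them Kdr, Plxnd1 (2.23 ± 0.11) and Nrp2 (0.67 ± 0.07; list median 0.11, adjusted p = 6.11e-06, but adjusted p = 0.201 with an estimated correlation). Of 17 primitive streak genes 5 rose, among them Wnt3 (2.08 ± 0.24), Lhx1 (1.97 ± 0.40), Rspo3 (1.63 ± 0.28) and Eomes (0.40 ± 0.08), and 1 fell (median 0.34, adjusted p = 0.00453, but adjusted p = 0.187 with an estimated correlation).

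The largest decreases were in genes of neurons and neural progenitors: Neurod4 (-1.88 ± 0.16), Chrna3 (-1.74 ± 0.18), Pou3f3 (-1.74 ± 0.29), Pou3f2 (-1.72 ± 0.30) and Glra1 (-1.49 ± 0.24), with the retinal gene Mpp4 (-1.55 ± 0.26). In the neuroectoderm list Zic1 fell (-1.21 ± 0.22) and 21 of 22 genes did not pass (median -0.17, adjusted p = 0.000832, but adjusted p = 0.139 with an estimated correlation). Isl1 (-1.43 ± 0.29) fell in the cardiac list (median -0.40, adjusted p = 0.0292, but adjusted p = 0.562 with an estimated correlation). The smaller shifts were mitochondrial RNA (median 0.31, 4 of 13 rose, adjusted p = 0.000832, but adjusted p = 0.341 with an estimated correlation), glycolysis (median 0.15, 2 of 22 rose, adjusted p = 0.0108, but adjusted p = 0.52 with an estimated correlation) and p53 targets (median 0.08, 1 of 20 rose, adjusted p = 0.0292, but adjusted p = 0.366 with an estimated correlation). Pluripotency genes had a median of -0.05 with Klf5 (-0.25 ± 0.05) fallen (adjusted p = 0.0292, but adjusted p = 0.599 with an estimated correlation). Germline genes had a median of -0.23 (adjusted p = 0.0178, but adjusted p = 0.511 with an estimated correlation) and 2-cell-like genes of -0.69 (adjusted p = 0.00844, but adjusted p = 0.52 with an estimated correlation). Endoderm (adjusted p = 0.724), trophoblast (0.798), fibroblast (0.265), H3K9 demethylase (0.963), H3K9 methylation (0.963) and stress response genes (0.34) were not called. The H188A DOX libraries differed in endoderm RNA: of 18 endoderm genes at 1 CPM or more, 17 were higher in replicate 1 than the mean of the other 2, by a median of 1.04 on the log2 scale. Without replicate 1 the endoderm list fell (median -0.27), and without replicate 2 or 3 it rose (0.33 and 0.31).

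In the H188A line 637 of 21086 genes changed, 468 up and 169 down, or 63 and 41 with an absolute log2 change of at least 1, with 12 of 18 lists called by camera at the preset correlation, 0 at an estimated one, and 4 at an unadjusted p under 0.05 with the latter. This count rested on single libraries: it was 203 without control replicate 1, 81 without control replicate 2, 1839 without control replicate 3, 140 without DOX replicate 2 and 91 without DOX replicate 3. The balance of directions was no firmer: 73.5% of the changed genes were up, but 41.2% without control replicate 3 and 55.1% with the stricter low-count filter. Counts in olfactory, vomeronasal and trace-amine receptor genes, normally silent outside sensory neurons, summed to 550.1, 168.7 and 35.36 CPM in the 3 control libraries and to 42.28 ± 28.99 CPM with DOX; with that sum as a covariate, 126 genes passed. The endothelial median with the covariate was 1.31 and the hematopoietic median 1.18, while the cardiac (-0.06) and glycolysis (0.10) calls ended.

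**Figure D3:**
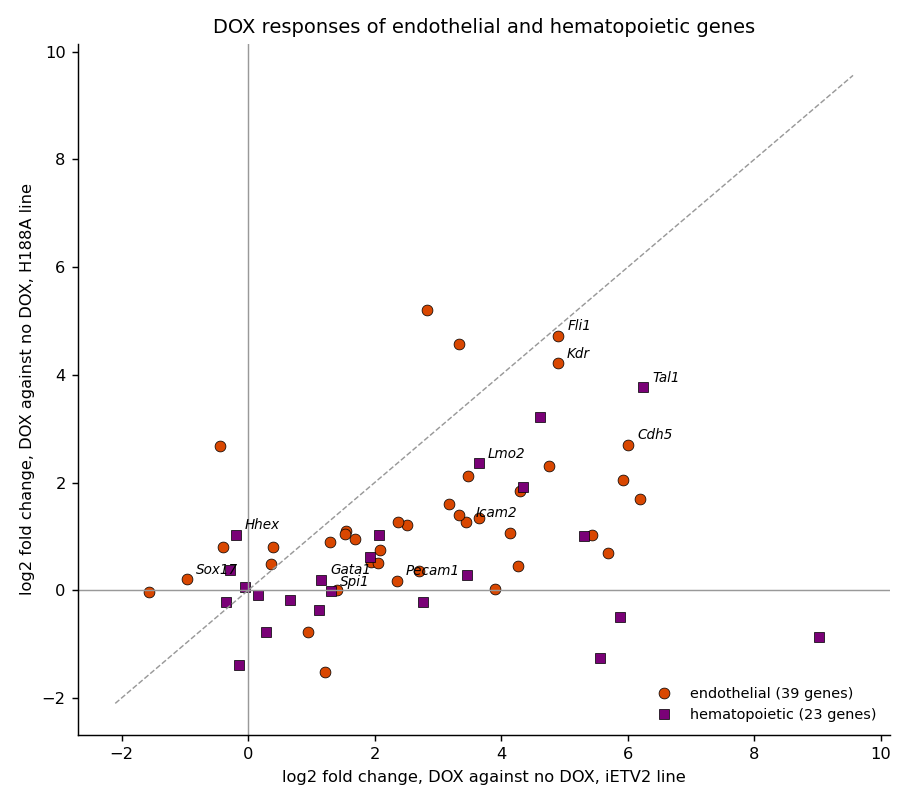
Log2 change with DOX in iETV2 (horizontal) against the H188A line (vertical) for endothelial and hematopoietic genes tested in both; each point is a gene and the dashed line marks equal change. Of 39 endothelial genes 31 lay below the line, and of 23 hematopoietic genes 19.

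Whether DOX acted differently in the H188A line was tested directly, as the interaction of line and treatment. The blood and endothelial response was smaller in the H188A line, although Etv2 itself rose by more there (difference of log2 changes 2.81 ± 0.36, adjusted p = 5.26e-05) and reached a similar level with DOX (15.2 ± 3.5 against 18.6 ± 0.89 CPM; -0.20 ± 0.19, adjusted p = 0.437). Negative differences mean a smaller increase or a larger decrease in the H188A line. The endothelial list differed by a median of -1.40 (20 of 40 genes lower, 7 higher; adjusted p = 2.75e-17, and 0.0273 with an estimated correlation), with Tek at -3.79 ± 0.11, Cdh5 at -3.29 ± 0.24 and Pecam1 at -2.16 ± 0.11. Several of these genes were already higher in the H188A line without DOX: Mmrn2 by 4.45 ± 0.17, Tek by 3.91 ± 0.09, Pecam1 by 3.26 ± 0.09, Eng by 2.81 ± 0.11, Cdh5 by 2.23 ± 0.20 and the blood gene Runx1 by 2.08 ± 0.13. Their smaller increase was thus measured against a higher untreated level. With DOX Tek stood at 41.5 ± 1.2 CPM in the H188A line and 40.7 ± 0.83 in iETV2, and Eng, Mmrn2 and Pecam1 were still higher in the H188A line. The hematopoietic list also differed by a median of -1.40 (15 of 28 lower, 2 higher; adjusted p = 6.45e-13, but adjusted p = 0.0506 with an estimated correlation), with Tal1 at -2.44 ± 0.35, Runx1 at -2.98 ± 0.17 and Hba-x at -9.72 ± 1.04. No difference passed the test for Kdr (-0.65 ± 0.34, adjusted p = 0.239), Fli1 (-0.13 ± 0.48, adjusted p = 0.896), Gata2 (-1.35 ± 0.57, adjusted p = 0.138) or Kdm4a (0.06 ± 0.10, adjusted p = 0.703). With the receptor sum as a covariate the median difference over the 68 genes of both lists was -0.78 in place of -1.40.

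Cardiac mesoderm genes showed the same direction (median -1.09, adjusted p = 7.21e-14, and 0.0273 with an estimated correlation), with Hand1 at -7.32 ± 0.19. Pluripotency (13 of 28 lower, 4 higher; median -0.33, adjusted p = 1.36e-18, and 0.0273 with an estimated correlation) and germline genes (16 of 21 lower, 0 higher; median -1.29, adjusted p = 3.6e-09, and 0.0129 with an estimated correlation) differed in the same direction. Neither list had a gene that rose in the H188A line, and their rise in iETV2 was called with the preset correlation only. Both lists were already higher in the H188A line without DOX (medians 2.40 and 3.07). Their smaller response was thus measured against a higher untreated level. Neuroectoderm (median 0.66, adjusted p = 1.67e-10, and 0.00339 with an estimated correlation) and glycolysis genes (median 0.97, adjusted p = 2.26e-46, and 0.00488 with an estimated correlation) were positive, since their fall in iETV2 was not matched in the H188A line. Glycolysis genes were already lower in the H188A line without DOX (median -0.85). With DOX that list was not called between the lines (median 0.09, camera adjusted p = 0.324). Calls lost with an estimated correlation were primitive streak (median -1.04, adjusted p = 0.00117, but adjusted p = 0.152 with an estimated correlation), fibroblast (-0.83, adjusted p = 0.000217, but adjusted p = 0.0596 with an estimated correlation), stress response (-0.62, adjusted p = 1.22e-05, but adjusted p = 0.148 with an estimated correlation) and H3K9 demethylase genes (0.11, adjusted p = 0.0132, but adjusted p = 0.436 with an estimated correlation). VEGF and Notch (adjusted p = 0.0663), endoderm (0.553, with a median of -0.24 and a test direction of up), trophoblast (0.0519), 2-cell-like (0.17), H3K9 methylation (0.676), p53 (0.483) and mitochondrial genes (0.159) were not called. In all, 3679 of 25516 genes differed, 2098 with a higher and 1581 with a lower response in the H188A line, around a median of -0.131 for all genes. With an absolute difference of at least 1 the balance was reversed, 626 higher and 902 lower.

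The lines were also compared without DOX. The labels do not say when these untreated libraries were taken, so they need not show the state before DOX. The lines also belong to different experiments (1 and 2). The H188A line had far less RNA of early mesoderm and more of pluripotency genes. T, the defining gene of the primitive streak, was at 862 ± 28 CPM in iETV2 and 0.357 ± 0.19 CPM in the H188A line, and Mixl1 at 74.9 ± 4.2 against 0.479 ± 0.14 CPM. Of the 22 primitive streak genes 20 were lower and 1 higher (median -4.17, adjusted p = 6.03e-71, and 0.000724 with an estimated correlation). Of the 28 pluripotency genes 23 were higher and 2 lower (median 2.40, adjusted p = 3.64e-59, and 0.00168 with an estimated correlation), with Esrrb at 3.80 ± 0.10 and Sox2 at 2.16 ± 0.10; Nanog did not pass (0.17 ± 0.07, adjusted p = 0.0809). Etv2 was lower (-3.01 ± 0.30) and Kdm4a did not pass (0.02 ± 0.07, adjusted p = 0.867).

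Germline genes were higher in the H188A line, 20 of 21 (median 3.07, adjusted p = 1.48e-18, and 0.00168 with an estimated correlation), among them Hormad1 (5.08 ± 0.22). VEGF and Notch genes (16 of 24 lower, 4 higher, median -0.81; adjusted p = 1.98e-09, and 0.0407 with an estimated correlation) and glycolysis genes (19 of 22 lower, 2 higher, median -0.85; adjusted p = 3.56e-17, and 0.0407 with an estimated correlation) were lower. Calls lost with an estimated correlation were neuroectoderm (median 0.54, adjusted p = 0.027, but adjusted p = 0.134 with an estimated correlation), fibroblast (-0.12, adjusted p = 0.0113, but adjusted p = 0.198 with an estimated correlation), p53 targets (0.56, adjusted p = 2.65e-05, but adjusted p = 0.198 with an estimated correlation), mitochondrial RNA (0.48, adjusted p = 0.0288, but adjusted p = 0.445 with an estimated correlation) and 2-cell-like genes (12 of 16 higher; median 4.42, which stays with genes at 0 counts placed at 3; adjusted p = 0.00654, but adjusted p = 0.424 with an estimated correlation). Endothelial (median 0.42, adjusted p = 0.78) and hematopoietic genes (median 0.11, mean -0.15, test direction down, adjusted p = 0.396) were not called, nor were cardiac (0.396), endoderm (0.0906), trophoblast (median 0.33, test direction down, 0.11), stress response (0.203), H3K9 demethylase (0.592) and H3K9 methylation genes (0.299). In the endoderm list 13 of 22 genes were nevertheless higher in the H188A line and 5 lower, with a median of 1.42. The largest increases were Srgn (8.55 ± 0.55), Cubn (7.33 ± 0.30), Aqp8 (6.99 ± 0.62), Habp2 (6.27 ± 0.45), Klb (5.74 ± 0.44) and Tuba3a (5.72 ± 0.27). Srgn and Cubn varied widely between the H188A libraries with DOX (89.2 ± 63 and 432 ± 190 CPM).

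Transcripts of the Y chromosome were near 0 in the H188A line. Eif2s3y had 8285 counts in iETV2 and 0 in the H188A line without DOX, at least 2760-fold lower against a floor of 3 counts over the group; Uty (-10.35 ± 0.27) and Ddx3y (-10.03 ± 0.25) were also lower. Aplnr, the apelin receptor gene of early mesoderm, was lower by -9.22 ± 0.28 on the log2 scale, and Defa30 at least 158-fold. Without DOX 9763 of 25516 genes differed between the lines, 5025 higher and 4738 lower in the H188A line, around a median of 0.103 for all genes. With an absolute difference of at least 1, 2199 were higher and 1580 lower. The balance was not firm: 51.5% of the differing genes were higher, but 39.1% without a low-count filter.

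With DOX, 9587 genes differed, 5088 higher and 4499 lower, but 1784 higher and 2158 lower with an absolute difference of at least 1, and 14 of 18 lists were called. Primitive streak genes were again lower in the H188A line (21 of 22, median -5.35, adjusted p = 3.76e-113, and 0.000109 with an estimated correlation). So were hematopoietic (21 of 28, median -2.13; 0.0363 with an estimated correlation), VEGF and Notch (17 of 24, median -1.26; 0.0128), cardiac (12 of 21, median -1.25; 0.0363), fibroblast (11 of 19, median -1.43; 0.0133) and trophoblast genes (7 of 18, with 5 higher, median -0.57; 0.0363). Pluripotency (25 of 28, median 1.52; 0.0128 with an estimated correlation), germline (17 of 21, median 1.70; 0.0128) and neuroectoderm genes (13 of 22, median 1.07; 0.0015) were higher, and Sox1 was so by 5.03 ± 0.20. Calls lost were endothelial (23 of 40 lower, median -1.17, adjusted p = 3.04e-09, but adjusted p = 0.066 with an estimated correlation), endoderm (1.44, adjusted p = 0.00222, but adjusted p = 0.449 with an estimated correlation), 2-cell-like (2.79, adjusted p = 0.0219, but adjusted p = 0.451 with an estimated correlation), p53 (0.62, adjusted p = 2.89e-07, but adjusted p = 0.066 with an estimated correlation) and stress response genes (-0.46, adjusted p = 2.34e-06, but adjusted p = 0.0934 with an estimated correlation).

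Experiment 3 compared control cells with the libraries labelled DKO, asking what loss of KDM4A and KDM4C changes. The control libraries carried more RNA of blood, endothelial and heart genes, and the DKO libraries more of pluripotency genes. Tal1 was at 171 ± 1.5 CPM in control and 5.82 ± 0.17 in DKO (log2 change -5.0 ± 0.05), Runx1 at 205 ± 6.2 and 14.7 ± 0.43, Hba-x at 367 ± 18 and 0.436 ± 0.2, and Cdh5 at 51.7 ± 1 and 2.76 ± 0.24 CPM. Nanog was at 6.98 ± 0.75 CPM in control and 210 ± 5.1 in DKO (4.79 ± 0.05), Pou5f1 at 22.8 ± 0.53 and 369 ± 18, and Sox2 at 4.6 ± 0.47 and 110 ± 1.8 CPM. The labels call both groups embryonic stem cells and give no day of culture.

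RNA of the named targets moved little. Kdm4a (ENSMUSG00000033326, chromosome 4, 118136957 to 118180090) fell from 54.6 ± 0.94 to 43.9 ± 2.6 CPM (-0.44 ± 0.05, adjusted p = 6.82e-08). Kdm4c (ENSMUSG00000028397, chromosome 4, 74242497 to 74405864) rose from 30.7 ± 1.3 to 45.5 ± 2.6 CPM (0.45 ± 0.06, adjusted p = 5.02e-07), and Kdm4b fell by 0.18 on the log2 scale. Counts per gene cannot show a deleted exon. Etv2 fell from 8.05 ± 0.67 to 2.92 ± 0.45 CPM (-1.58 ± 0.13).

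In the hematopoietic list, 27 of 27 measured genes fell (median -4.45, adjusted p = 1.56e-67, and 0.0203 with an estimated correlation), with the embryonic globin Hbb-bh1 at -8.50 ± 0.08, Hbb-y at -10.51 ± 0.16 and Gata2 at -3.23 ± 0.06. In the endothelial list 33 of 38 fell and 3 rose (median -1.86, adjusted p = 1.67e-20, and 0.019 with an estimated correlation), including Fli1 (-4.51 ± 0.08), Egfl7 (-3.04 ± 0.06), Kdr (-2.19 ± 0.04) and Pecam1 (-1.88 ± 0.05). Cardiac mesoderm genes fell in 17 of 21 and rose in 3 (median -1.77, adjusted p = 3e-09, and 0.0203 with an estimated correlation), led by Hand1 (599 ± 21 to 9.73 ± 0.85 CPM). Fibroblast genes fell in 14 of 20 and rose in 5 (median -1.60, adjusted p = 5.21e-13, and 0.0212 with an estimated correlation), with Col1a1 at -4.96 ± 0.05. VEGF and Notch genes fell in 15 of 23 and rose in 7 (median -0.72, adjusted p = 0.000319, and 0.0364 with an estimated correlation), with Plxnd1 at -2.91 ± 0.05. The 17 trophoblast genes moved both ways, 8 up and 8 down. The median was 0.20, the mean -0.38 and the test direction down (adjusted p = 7.12e-07, and 0.032 with an estimated correlation). Peg10 went from 3370 ± 49 to 12.4 ± 1.2 CPM and Cdx2 changed by -4.48 ± 0.07. Gata5 had 1209 counts in control and 2 in DKO, a ratio of 524 (95% counting interval 145 to 4340), and Hoxb6 fell by 8.23 ± 0.15.

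Of the 28 pluripotency genes 24 rose and 2 fell (median 4.05, adjusted p = 1.2e-69, and 0.0121 with an estimated correlation), with Esrrb at 5.62 ± 0.06, Tfcp2l1 at 4.94 ± 0.05, Nr0b1 at 6.98 ± 0.14, Tcl1 at 6.44 ± 0.22 and Tdgf1 at 3.36 ± 0.04. Neuroectoderm genes rose in 15 of 18 (median 1.58, adjusted p = 1.42e-12, and 0.0121 with an estimated correlation), with the epiblast genes Otx2 (5.64 ± 0.07) and Fgf5 (6.41 ± 0.17). Germline genes rose in 18 of 19 (median 2.19, adjusted p = 0.00095, and 0.0377 with an estimated correlation), with the meiotic gene Sycp3 at 3.80 ± 0.12. In the primitive streak list 14 of 22 rose and 7 fell (median 0.92, adjusted p = 0.0234, but adjusted p = 0.232 with an estimated correlation); T rose from 64.1 ± 1.2 to 255 ± 9.8 CPM, Nodal by 4.73 ± 0.06 and Eomes by 2.13 ± 0.04. The hormone precursor gene Trh (6.60 ± 0.05), Foxd3 (7.17 ± 0.27) and Serpina3m (7.27 ± 0.28) were among the largest increases, and Platr12 had 850 counts in DKO against 3 in control, a ratio of 327 (95% counting interval 111 to 1590).

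The p53 target list rose (14 of 20, with 4 fallen; median 0.64, adjusted p = 0.0016, but adjusted p = 0.263 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 1.19 ± 0.04. Stress response genes (15 of 20 fell and 4 rose; median -0.56, adjusted p = 0.00144, but adjusted p = 0.263 with an estimated correlation) and glycolysis genes (18 of 21 fell and 2 rose; median -0.50, adjusted p = 3.17e-05, but adjusted p = 0.263 with an estimated correlation) fell. Among them were Slc2a1 at -1.41 ± 0.04 and Vegfa at -1.52 ± 0.05. Endoderm (adjusted p = 0.483), H3K9 demethylase (0.304), H3K9 methylation (0.483) and mitochondrial genes (0.197) were not called, though mitochondrial RNA made up 3.672 ± 0.04786% of counts in control and 5.252 ± 0.4246% in DKO. In all, 14153 of 20426 genes changed, 7268 up and 6885 down. With an absolute log2 change of at least 1, 4011 rose and 1795 fell.

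**Figure D4:**
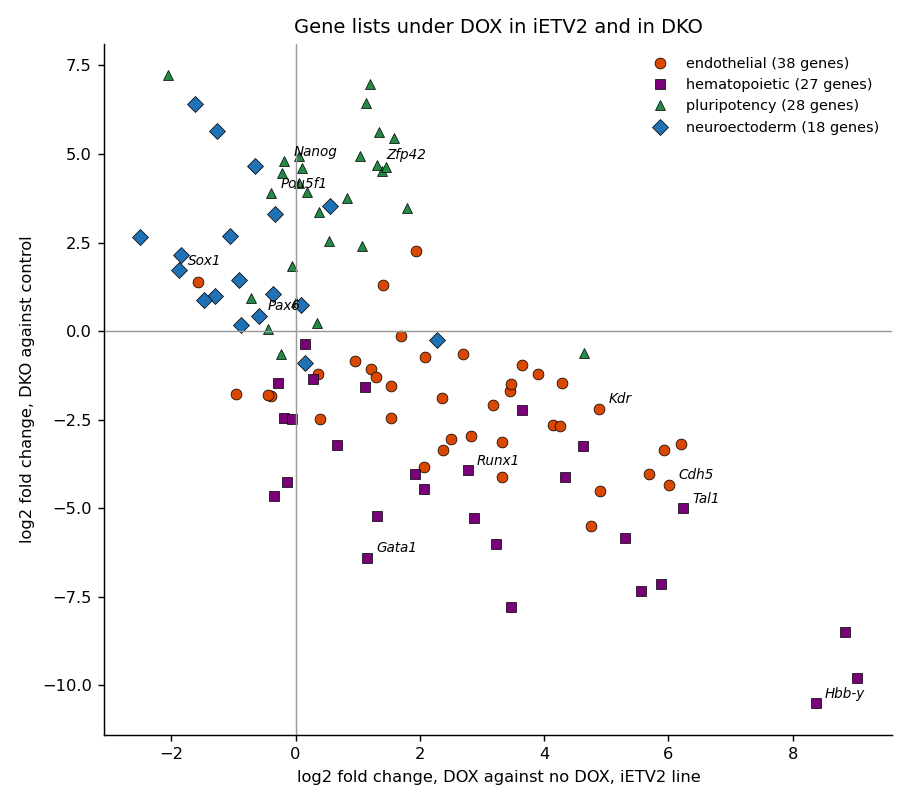
Log2 change with DOX in iETV2 (horizontal) against log2 change in DKO (vertical) for members of 4 lists; each point is a gene. Of 38 endothelial genes 34 lay above 0 with DOX and 3 in DKO, and of 27 hematopoietic genes 22 and 0. Of 18 neuroectoderm genes 4 lay above 0 with DOX and 16 in DKO. Pluripotency genes lay mostly above 0 in both, 19 of 28 with DOX and 26 in DKO.

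Whether the genes that respond to DOX in iETV2 also move in DKO was asked across all of them. Genes that rose with DOX had a median change of -0.176 in DKO, against 0.065 for the rest (2965 genes, adjusted p = 0.00737, but adjusted p = 0.286 with an estimated correlation). Genes that fell with DOX had a median of 0.295, against 0.004 for the rest (2788 genes, adjusted p = 0.00149, and 0.0211 with an estimated correlation). By calls, 1494 genes rose with DOX and fell in DKO where 1033 were expected for independent calls (odds ratio 2.15, Fisher's exact test p = 1.01e-79), and 1407 fell with DOX and rose in DKO where 974.3 were expected (odds ratio 2.13). For the genes that rose in the H188A line, 352 of 468 fell in DKO where 162.5 were expected (odds ratio 5.97). The H188A calls rested on single libraries, as given above, and 18.4% of all of them were kept with the receptor covariate. This odds ratio is therefore no firmer than those for iETV2. Between the lines, 193 genes rose with DOX in both where 67.85 were expected (odds ratio 4.36). Opposite calls were also in excess in 1 direction, with 40 genes risen in iETV2 and fallen in the H188A line where 23.63 were expected (odds ratio 1.93, Fisher's exact test p = 7e-04). Over all genes the changes in the lines correlated at 0.16 (Pearson) and 0.08 (Spearman). Genes are not independent replicates, so these Fisher tests measure overlap only.

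Experiment 4 asked whether DOX changes H3K9me3. Only the number and extent of called regions were compared, which do not measure the level of the mark. The DOX libraries held 45342 ± 5879 enriched regions and the untreated libraries 39443 ± 3607 (mean ± SD, n = 3 each; two-sided exact permutation p = 0.2), and the regions covered 244.7 ± 45 and 264.1 ± 31.4 Mb (exact p = 0.5). With 3 libraries against 3 the smallest exact p is 0.1, so this test could not pass 0.05 and shows neither a difference nor its absence. The DOX libraries carried 3 different titles: EB-DOX-D2 (50838 regions, 294.8 Mb), EB-DOX-D3 (39144, 231.7 Mb) and EB-Er71-Flag-DOX-D2 (46044, 207.7 Mb). What these titles distinguish is not given in the sources used here, so the DOX group may mix conditions, and its mean, SD and p would then span them. The untreated libraries had 37600, 37129 and 43599 regions over 233.9, 296.5 and 262.0 Mb. The Y chromosome alone accounted for 33.49 to 77.65 Mb per library; on chromosomes 1 to 19 the covered length was 180.9 ± 27.4 Mb with DOX and 183.7 ± 14.6 Mb without.

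**Figure D5:**
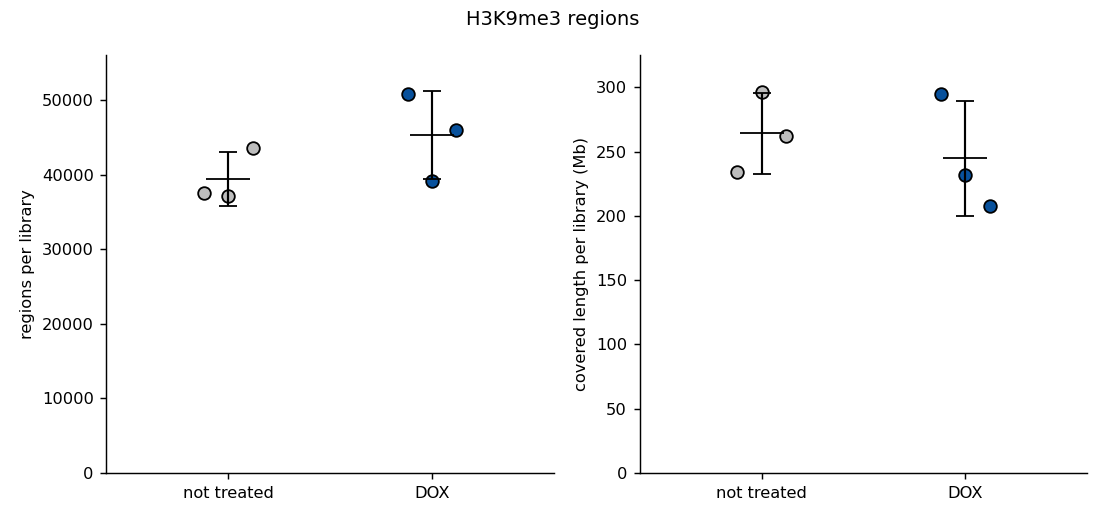
Number of H3K9me3 regions and length covered in Mb for each ChIP library, by group; points are libraries and bars are means ± SD (n = 3). The groups overlap in both: regions from 37129 to 50838 and covered length from 207.7 to 296.5 Mb.

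Merged over the 6 libraries there were 49152 regions, of which 19238 (39.1%) were found in all 6. In every DOX library and no untreated one there were 566 regions, and in every untreated library and no DOX one 142. The longest of the former lay at chromosome 14, 53425201 to 53435800, in the T-cell receptor alpha locus (Tcra, Trav6-3), at chromosome 4, 87041601 to 87050000, within Slc24a2, and at chromosome 4, 89235401 to 89243800, which overlaps no annotated gene and is 30673 bp from Cdkn2a. The longest of the latter lay at chromosome 5, 11042401 to 11056200, chromosome X, 149495001 to 149508400, and chromosome 13, 61595201 to 61607600, the first 2 over pseudogenes. Without single libraries these counts ranged from 779 to 1499 and from 213 to 651; each left-out library moved at least 1 of them by more than 1.5 times, as fewer libraries have to share a region.

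Regions were looked up within 5 kb of the named genes. No region was called in any library at Kdr, Tal1, Gata2, Fli1, Pecam1, Pou5f1, Nanog, Sox2, Etv2 or Kdm4c. Cdh5 held 1 region, inside the gene at chromosome 8, 104114201 to 104120400, in untreated replicate 1 alone (241 ChIP and 185 input reads, log2 enrichment 0.39), and Kdm4a had regions in all 6 libraries. Region lists give no value where nothing was called, so a level below the authors' threshold cannot be told from none.

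Genes that changed in the RNA comparisons differed in how often an H3K9me3 region, found in at least 2 untreated libraries, lay within 5 kb of either gene end. Each set was compared with all other tested genes, including those changed in the opposite direction, so the 2 tests of a comparison lean on each other. Genes were not matched for expression level and are not independent replicates. Of the genes higher in DKO 15.5% had one, against 10.5% of the other tested genes (odds ratio 1.56, Fisher's exact test, adjusted p = 3.72e-20), and of the genes lower in DKO 8.73% against 14.3% (odds ratio 0.573, adjusted p = 1.21e-27). For genes that fell with DOX in iETV2 the shares were 9.48% and 12.9% (odds ratio 0.705, adjusted p = 4.12e-07), and for genes that rose in the H188A line 7.11% and 12.7% (odds ratio 0.525, adjusted p = 0.000365). The shares did not differ by this test for genes that rose with DOX in iETV2 (12.1% and 12.5%, adjusted p = 0.665) or fell in the H188A line (10.9% and 12.6%, adjusted p = 0.688). The labels do not name the line used for ChIP or link its samples to those sequenced for RNA.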

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

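The tests of Etv2 in proportion and of the state without DOX and the kind of splits used here were chosen only after the results were seen. The receptor covariate was added after the data were seen, with its bound written before its result.

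The response to DOX differed between iETV2 and the H188A line by the interaction test in 3679 genes, in 11 gene lists and in the genes named here; values are the H188A change minus the iETV2 change, on the log2 scale. List medians were endothelial -1.40, hematopoietic -1.40, pluripotency -0.33, primitive streak -1.04, cardiac mesoderm -1.09, neuroectoderm 0.66, fibroblast -0.83, germline -1.29, H3K9 demethylases 0.11, integrated stress response -0.62 and glycolysis 0.97. Primitive streak, hematopoietic, fibroblast, demethylase and stress response lists lost their call with an estimated correlation (adjusted p = 0.152, 0.0506, 0.0596, 0.436 and 0.148).

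Endothelial and blood genes that differed were Tek -3.79, Mmrn2 -3.87, Cdh5 -3.29, Eng -2.34 and Pecam1 -2.16, and Tal1 -2.44, Runx1 -2.98, Hba-x -9.72, Hbb-bh1 -9.64 and Hba-a1 -6.70. Etv2 itself had 2.81, Kdm4b 0.60, Kdm4c 0.40, Kdm3a 0.66 and Kdm7a 0.62. Mesodermal genes were Hand1 -7.32, Bmp4 -3.39, Isl1 -3.02, Foxf1 -4.25, Cdx4 -6.11, Evx1 -4.26, Hoxb1 -2.78 and Fgf3 -2.37, with the antisense transcript Evx1os at -6.40. Pluripotency genes were Pou5f1 0.53, Tbx3 -4.72, Dppa5a -1.57, Dppa4 -1.79 and Nr5a2 -1.44. Neuroectoderm genes were Pou3f1 2.36, Fgf5 1.69, Otx2 1.33 and Zic2 1.09. Genes of cilia and node were Cfap206 5.21, Tekt2 4.71, Iqub 4.66, Dnajb13 4.60 and Enkur 4.28, and Foxd4, on none of the lists, had 6.45. Fibroblast genes were Fn1 -2.21, Pdgfrb -1.52, Fbn1 -0.75 and Twist2 -3.81, germline genes Tex11 -2.03, Stag3 -0.74, Piwil2 -1.09 and Rpl10l -2.03, stress response genes Slc7a11 -1.94, Vldlr -0.90, Psat1 -0.63 and Asns -0.61, and glycolysis and hypoxia genes Ndrg1 2.44, Bnip3 2.10, Slc2a1 1.70 and Ddit4 1.80. Several of these genes had few counts in the H188A line, summed over the group without and with DOX. They were Evx1os (87 and 10), Cdx4 (66 and 28), Twist2 (72 and 28), Hba-a1 (41 and 17), Hba-x (28 and 16) and Hbb-bh1 (30 and 16). The size of their differences is therefore uncertain. As no Etv2-independent DOX control was analysed here, effects of DOX itself are part of each response.

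The smaller response of blood and endothelial genes in the H188A line was weighed against 3 explanations. If it followed a lower Etv2 level in proportion, the genes of both lists would differ between the DOX groups by no more than Etv2 does, but their median was -1.41 (95% interval -1.72 to -1.10, all 68 genes), below the bound of -0.58 that Etv2 allows. Over the 9 pairs of DOX libraries it ranged from -1.50 to -1.30, and that of Etv2 from -0.69 to 0.15. The interval comes from draws of genes, with estimated correlations of 0.19 (endothelial) and 0.28 (hematopoietic), so it is too narrow. The test covers only total Etv2 RNA when sampled and a response in proportion to it. Counts per gene cannot tell transgene from endogenous Etv2, so a lower transgene level is not excluded. The endothelial list alone (-1.17) lost its call with an estimated correlation (adjusted p = 0.066). Reads in silent receptor genes stay open: with them as a covariate the median interaction of 68 genes was -0.78 (-1.36 to -0.41), against -1.40 (-2.22 to -1.24) without, and the interval includes the bound of -0.5 set for this test. A different state of the lines without DOX may also underlie it, since primitive streak genes differed there by a median of -4.17 (-6.09 to -2.53). Line, clone, experiment and mutant KDM4A cannot be told apart in this design. An effect of the mutant KDM4A is therefore an open, untested explanation, and the Kdm4a counts do not show that the mutant was expressed.

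In 40 splits that redrew the DOX labels in both lines, the real one gave 3679 genes and the highest other 2418, and 11 and 14 lists. Those that mix iETV2 libraries put the DOX effect of that line into the residual spread and gave at most 1 gene, so these 40 were not used to judge chance. With the iETV2 groups kept and only the H188A libraries redrawn there are 20 splits, too few for a share under 0.05: the real one gave 3679 genes, with 4612 as the highest other, and 11 lists, with 15 as the highest other. At least as many genes came from 4 splits and as many lists from all 20, the real one included. Each split keeps the iETV2 response, so these counts hold that response as well as any difference between the lines.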

How the results depend on the processing

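The receptor covariate and the restriction to protein-coding genes were chosen after seeing the data. Apart from the values below, the counts of changed genes stayed within 1.5 times under DESeq2 size factors, the DESeq2 Wald test, both other low-count filters, protein-coding genes only, fits with all 12 or 18 libraries and the covariate. Of the values recomputed for single named genes 6068 kept direction and side of the threshold, 164 lost and 22 gained their call; for lists these numbers were 1288, 62 and 25. The endoderm list, not called with all libraries in the H188A line (0.13) or the interaction (-0.24), reversed its test direction and was called without H188A DOX replicate 1, with medians of -0.27 and -0.69, the lowest of its leave-one-out values. The highest, without DOX replicate 2, were 0.33, called, and -0.04, not called. Replicate 1 held more endoderm RNA than the other 2, by a median of 1.04.

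The H188A count of 637 became 423 with DESeq2 size factors, 2032 without a low-count filter, 979 with the DESeq2 Wald test and 126 with the covariate, which kept 117 of the calls; the cause was not tested. With an absolute log2 change of at least 1, counts were 1864 for iETV2, 104 for the H188A line, 1528 for the interaction, 3779 and 3942 between the lines without and with DOX, and 5806 for DKO, as fewer genes can pass. For iETV2 sets limited in this way the median changes in DKO were -0.597 (risen) and 0.829 (fallen), in place of -0.176 and 0.295. With an estimated correlation, lists called fell to 6 in iETV2, 0 in the H188A line (camera, 4 at unadjusted p under 0.05), 6 for the interaction, and 5 and 9 between the lines; the DKO response of genes risen with DOX kept its median of -0.176 but not its call (p = 0.286).

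Deviations from the group means of libraries with equal replicate numbers correlated at -0.01, 0.32 and 0.56 in iETV2, -0.21, 0.15 and 0.35 in the H188A line and -0.01 to 0.01 in DKO. They were not above 0.1 in every pair, and not every library correlated best with its own number, so the numbers were not taken to pair samples. With the replicate number as a block, counts were 8380 for iETV2, 263 for the H188A line, 4849 for the interaction, 9311 and 8970 between the lines without and with DOX, and 13926 for DKO. Leaving out each library in turn gave 4577 to 6731 genes for iETV2, 81 to 1839 for the H188A line (main 637; without control 2 and control 3), 2585 to 4112 for the interaction, 8201 to 9738 and 7634 to 10029 between the lines, and 13349 to 14513 for DKO. Lists called were 12 to 14, 9 to 12, 11 to 14, 10 to 12, 14 and 13. The DKO response ranged from -0.195 to -0.143 and from 0.274 to 0.326. The difference in H3K9me3 regions ranged from 3151 to 8998 and in covered length from -44.4 to -0.9 Mb, and regions in 1 group alone from 213 to 651 for untreated and 779 to 1499 for DOX libraries, as fewer libraries had to share them. Requiring libraries to cover at least 50% of a region, and taking a library below that as absent, gave 326 regions on the untreated side in place of 142. The rise comes from the looser rule for absence, so DOX libraries may hold smaller parts of these regions. On the DOX side the count was 478 in place of 566. The calls for regions near either gene end were the same in each alternative run, but their sizes moved. For genes that fell with DOX in iETV2 the odds ratio was 0.705 in the main run, 0.424 with a 1 kb window and 0.852 with a 10 kb window.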

Other observations

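The lists for cilia and node, imprinted, HOX and hindbrain genes, and the tests of counts taken by a few genes, of exchanged labels, of a block before mesoderm, of Y loss and of ChIP splits were chosen only after the results were seen. The bound of the Y loss test was rewritten after its result. As the added lists were chosen after looking at these same data, their p-values are descriptive and no independent test.

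Genes of motile cilia and the embryonic node fell nearly as a whole with DOX in iETV2: 38 of 40 fell, with a median of -3.88 (adjusted p = 1.1e-146, and 0.00231 with an estimated correlation). In the H188A line they were lower than in iETV2 without DOX (37 of 40, median -3.40, adjusted p = 0.00905 with an estimated correlation). With DOX 1 of 36 fell there (median -0.26, adjusted p = 0.00363, but adjusted p = 0.511 with an estimated correlation), and the responses differed by a median of 2.76 (0.00117 with an estimated correlation). In DKO 18 of 33 rose and 1 fell (median 0.91, adjusted p = 0.000632, but adjusted p = 0.264 with an estimated correlation). Shh, the signal of node and notochord, was at 28.2 CPM in iETV2 without DOX and 1.83 CPM with it.

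HOX genes rose in 24 of 37 with DOX in iETV2 (median 1.55, adjusted p = 3.95e-08, but adjusted p = 0.166 with an estimated correlation), while 4 of 18 fell in the H188A line (median -1.13, adjusted p = 1.43e-06, but adjusted p = 0.306 with an estimated correlation). In DKO 33 of 34 fell and 1 rose (median -4.70, adjusted p = 9.02e-18, and 0.00817 with an estimated correlation). Imprinted genes moved both ways in DKO, 20 of 35 down and 11 up (median -0.34, adjusted p = 2.39e-10, and 0.0368 with an estimated correlation): Peg10 fell as given above, while Meg3 went from 1.21 ± 0.56 to 66 ± 2.8 CPM. In iETV2 14 of 35 rose and 8 fell (median 0.16, adjusted p = 0.000733, but adjusted p = 0.166 with an estimated correlation). Hindbrain and spinal cord progenitor genes fell in 13 of 28 with DOX in the H188A line and rose in 1 (median -1.15, adjusted p = 1.03e-16, but adjusted p = 0.0832 with an estimated correlation); in iETV2 they were not called (median -0.59, test direction up, adjusted p = 0.952). Hprt rose with DOX in both lines, from 7.67 ± 0.59 to 119 ± 3.9 CPM in iETV2 and from 3.76 ± 0.46 to 50.5 ± 4.6 CPM in the H188A line.

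In DKO, blood genes were low and pluripotency genes high. Counts taken by a few genes are argued against: the 10 most counted genes held 7.52% of counts in control and 9.28% in DKO, which shifts all other genes by -0.03, while the hematopoietic median was -4.45. Exchanged group labels stay open, because Kdm4c was higher (0.45) and Kdm4a lower (-0.44) in the libraries labelled DKO. A block before mesoderm formation was not settled either. Its test took a higher primitive streak list as a sign of a block, and that list had a median of 0.92 but lost its call with an estimated correlation. These genes mark the earliest mesoderm, and 14 of 22 rose while 7 fell. A higher list therefore does not show a block before mesoderm, and this test cannot decide. A different stage of culture of the groups was not tested. The labels give a genotype but no cell line for these groups. Differences between lines or clones therefore cannot be told apart from the knockout.

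The H188A line had Y-linked transcripts near 0 and more Xist than iETV2 without DOX (62.2 ± 0.79 against 1.99 ± 0.33 CPM). Loss of the Y chromosome alone from an XY line would not raise Xist, which differed by 5.02 ± 0.17 on the log2 scale. An XX line with both X chromosomes active is argued against by X-linked genes, whose median lay -0.13 from the autosomal one (95% interval -0.22 to -0.05, 426 genes). An XX line with 1 silenced X may remain as an explanation, and the lines would then not share an origin. In experiment 3 Eif2s3y had 1 count in control and 4 in DKO, and Xist went from 0.916 ± 0.29 to 15.1 ± 1.4 CPM; X-linked genes lay 0.56 above autosomal ones (0.49 to 0.65, 438 genes), 79% of them higher in DKO against 41.4% of autosomal genes. The 6 ChIP libraries had 4864 to 9565 regions on the Y chromosome.

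With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5939 genes and 14 lists for iETV2 (highest other 0 genes by edgeR, with up to 2677 at unadjusted p under 0.05, and 11 lists), and 637 genes and 12 lists for the H188A line (17 and 9). Between the lines it gave 9763 genes and 10 lists without DOX (0 genes, up to 3370 unadjusted, and 12 lists, with 3 splits at 10 or more) and 9587 genes and 14 lists with DOX (0 genes, up to 1373 unadjusted, and 14 lists). For DKO it gave 14153 genes and 13 lists (0 genes, up to 133 unadjusted, and 10 lists), and the medians of the genes that rose and fell with DOX had sizes of 0.176 and 0.295, against 0.082 and 0.112 at most in other splits. For H3K9me3 the real split gave 708 regions found in 1 group alone, and the highest other 774.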
